A study of Zea mays with 48 samples.

How the data were processed

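RNA was measured in roots of maize seedlings of the inbred line B73, whose genome serves as the maize reference. Per the labels' protocols, seedlings were given tunicamycin at 5 µg/ml for 0, 3, 6, 12, 24, 36 or 48 h, with a mock treatment of 48 h beside them, and libraries were sequenced from both ends. The labels describe 8 groups of 3 libraries, with a sample from lane 6 and one from lane 7 for each, which gives 48 samples. In the 7 groups other than the mock, both lanes of a library carry one library name and one index. In the mock the index and the spelling of the name differ between the lanes of each number, so the labels do not show that one mock library ran on both lanes; they were summed by number, as in the deposited counts. Lane 7 of library II of the 24 h group was not analysed here. The remaining 47 lane samples and all 24 libraries were used.

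The labels of this series are not free of conflict. The sample titles and the time-point entries give different times to the lanes of some libraries, whereas the library name in the description of each sample gives a time and a library number (I, II or III) that both lanes share. Samples were grouped by library name, before the data were examined, and the grouping by title was kept as an alternative. The columns of the count table carry the library grouping as well. When the 47 lane samples were taken one by one, the common biological coefficient of variation was 0.256 under the library names and 0.289 under the titles.

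The deposited count table holds whole-number read counts per gene for 23753 genes and 24 libraries, and each equals the sum of the lanes of that library. A second deposited table holds RPKM values per lane, that is, reads scaled by gene length and library size. STAR, featureCounts and edgeR are named in the submitters' processing notes, with no version given. The genome build and the annotation version are not given in the sources used here. Because RPKM values keep whole reads when gene lengths are known, reads per lane and gene lengths were solved from the deposited RPKM and counts. Of the lane values, 100% came out whole within 0.001 reads, 100% of the lengths came out whole within 0.01 bp, and the lane reads summed to the deposited counts with a largest difference of 0. The recovered lengths ranged from 132 to 128400 bp with a median of 3513 bp. Whether they include introns is not given in the sources used here. The deposited table lists no gene with fewer than 152 reads over all libraries, so genes with little expression in these roots are not covered.

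Depth ranged from 7701856 to 38577551 reads per library with a median of 24966395. Library II of the 24 h group, with 1 lane, was the shallowest. Among lane samples, the range was 2020493 to 23222480 reads on lane 6 and 3862586 to 26076444 on lane 7. Whether reads were counted by strand, and how reads shared between near-identical gene copies were assigned, is not given in the sources used here. Counts of overlapping genes and of gene copies are uncertain to that extent.

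Differential expression was tested on the counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, in a single model of all 8 groups, so that every comparison shared 1 estimate of the spread. The low-count filter of edgeR removed 0 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2 scale, and each standard error was derived as the fold change divided by the root of its F statistic. Levels are in CPM, that is counts relative to the TMM-scaled library size, and given as mean ± SD of 3 libraries. For plots and set tests, log2 CPM was taken with a prior count of 2. On simulated counts with 200 changed genes for 48 h tunicamycin against 48 h mock, over 23753 genes, the same steps called 10% of genes changed 1.5-fold, 44% of those changed 2-fold, 88% of those changed 4-fold and 94% of those changed 8-fold, and called 7 unchanged genes. The simulated libraries were drawn independently of each other, which the real ones may not be.

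There were 10 comparisons. Each treatment time was set against 0 h, 48 h tunicamycin against 48 h mock, 48 h mock against 0 h, 12 h against 3 h, and 48 h against 12 h. Only 48 h has a mock group of its own age, so the other comparisons with 0 h hold both treatment and time in the bottles. The gene identifiers are not paired with names in the sources used here, and 0 of 23753 identifiers matched the reference table of 49888 genes. For that reason 25 gene lists fixed before the data were examined, on the unfolded protein response, cell death, root processes and cell types, could not be tested, and no chromosome or position is given. By the rule for named genes, the identifiers printed are the 2 with the largest rise and the 2 with the largest fall at 48 h against mock among called genes whose 3 treated libraries all lay on one side of the 3 mock libraries and whose mean was at least 5 CPM. In place of lists, the genes called in 1 comparison were followed in libraries outside the groups it compared, with camera of limma 3.58.1 (preset correlation, 38 tests, Benjamini-Hochberg adjusted). The model that called them drew its estimate of the spread from all 24 libraries, the followed ones included. Each camera test was repeated with an estimated correlation between genes. These sets were chosen after the data had been seen.

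The labels name 3 biological replicates, but p-values measure only the spread between these libraries, part of which may be technical. Library numbers recur in every group, so deviations of equally numbered libraries from their group means were correlated. Every pair correlated above 0.1 in 4 comparisons. The lowest correlation was 0.161 for 6 h against 0 h, 0.174 for 48 h against mock, 0.32 for 48 h mock against 0 h and 0.218 for 12 h against 3 h, which counts as pairing by number from the data and not from the labels. For these comparisons the fit with the library number as a replicate block is given wherever it moved a count by over 1.5 times.

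Alternatives were median-of-ratios scaling, DESeq2 1.42.0, no low-count filter, a minimum mean of 5 CPM, a replicate block, only the 2 groups compared, lane 6 or lane 7 alone, grouping by title, and each library left out in turn. After the data had been seen, 2 were added. One summed libraries I and II within each lane and kept library III whole, and the other left the 24 h libraries out of the model. The set tests were also run, again after the data had been seen, without library III of 12 h, of the mock or of both. For the chance check, each comparison was refitted on its 6 libraries under all 10 splits into 3 and 3. Lanes were compared by the chi-square of their counts and, with thinning of every lane to 2020493 reads, by a common biological coefficient of variation per pair. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.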

Results

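Tunicamycin blocks the first step of N-linked protein glycosylation, so that unfolded glycoproteins build up in the endoplasmic reticulum (ER). The series follows the root transcriptome of maize seedlings under such persistent stress, with 8 groups of 3 libraries: 0 h, 6 times of tunicamycin up to 48 h, and a 48 h mock. Read counts of 23753 genes were compared. Libraries held 16105148 to 24443472 reads at 0 h, 15998602 to 33236105 at 3 h, 30516970 to 38577551 at 6 h and 22436181 to 28823685 at 12 h. They held 7701856 to 27217665 reads at 24 h, 22472371 to 33489007 at 36 h, 26499235 to 28401358 at 48 h and 23314150 to 25489318 in the mock. The identifiers are not paired with gene names, so groups of genes are described by the comparison in which they were called. Adjusted p-values for single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

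The first principal component of log2 CPM held 26.6% of the variance and the second 14.04%. Libraries of 1 group did not always lie together. On the first component, library III of the mock lay at 53.1 and libraries I and II at -20.8 and -21.7, and library III of 12 h lay at 16.7 and libraries I and II at -51.2 and -45.4. Libraries I and II lay close to each other in most groups, as at 0 h (-60.0 and -61.3) and at 6 h (40.8 and 40.2). At 24 h the 3 libraries spread from -74.0 to 28.1. On the first 2 components, library III of 12 h (16.7 and 30.5) lay beside libraries I (16.9 and 31.1) and II (16.3 and 30.6) of 36 h. On the third they lay at 28.8, 36.2 and 47.9. Whether this library belongs to another time was not tested.

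**Figure D1:**
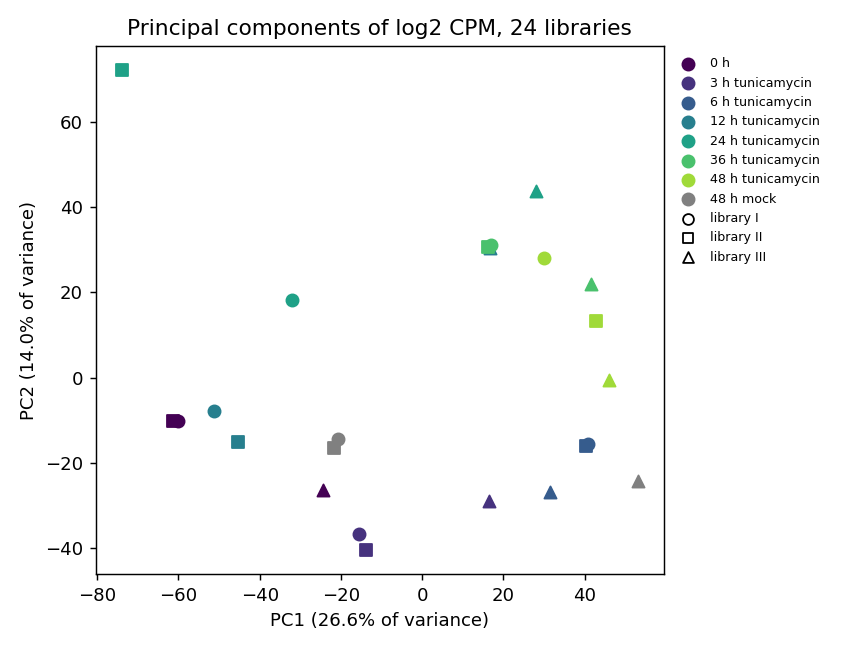
Principal components 1 (horizontal, 26.6% of variance) and 2 (vertical, 14.04%) of log2 CPM for the 24 libraries; colour gives the group, with the mock in grey, and marker shape gives library I, II or III. Libraries I and II of the mock lie at -20.8 and -21.7 on component 1 and library III at 53.1.

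The comparison of 48 h tunicamycin with 48 h mock asks which transcripts differed after prolonged treatment at equal age. Of 23753 genes, 80 rose and 32 fell. The risen genes had a median log2 fold change of 1.62 and a median level of 53.1 CPM against 20.2 CPM in the mock. The fallen genes had a median log2 fold change of -1.61 and a median level of 5.90 CPM against 16.2 CPM. At least 2-fold changes made up 66 of the risen and 27 of the fallen genes, and 24 and 10 genes changed at least 4-fold. Zm00001d049068 rose by 7.21 on the log2 scale (SE 0.61, adjusted p = 1.31e-06, edgeR), from 0.286 ± 0.141 to 43.4 ± 22.2 CPM (SD, n = 3 libraries each). Its 3 mock libraries held 8, 10 and 3 reads. Zm00001d024210 rose by 4.79 (SE 1.01, adjusted p = 0.0342, edgeR), from 1.91 ± 0.115 to 53.0 ± 11.3 CPM. Zm00001d041984 fell by 2.20 (SE 0.34, adjusted p = 0.0025, edgeR), from 165.6 ± 14.03 to 36.0 ± 17.1 CPM. Zm00001d019364 fell by 2.19 (SE 0.46, adjusted p = 0.0336, edgeR), from 15.3 ± 3.80 to 3.37 ± 2.16 CPM. Zm00001d024210 lost its call in 5 of 6 fits that left out 1 library (highest adjusted p 0.222, edgeR) and Zm00001d019364 in 4 of 6 (highest 0.268). The 80 risen and 32 fallen genes became 32 and 5, 34 and 4 or 139 and 53 without library I, II or III of 48 h, and 34 and 4, 35 and 6 or 63 and 56 without library I, II or III of the mock. They were 83 and 10 with only these groups in the model (42 genes shared with the main fit), 82 and 16 on lane 7, 58 and 18 with libraries I and II summed within each lane, and 172 and 91 with DESeq2.

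**Figure D2:**
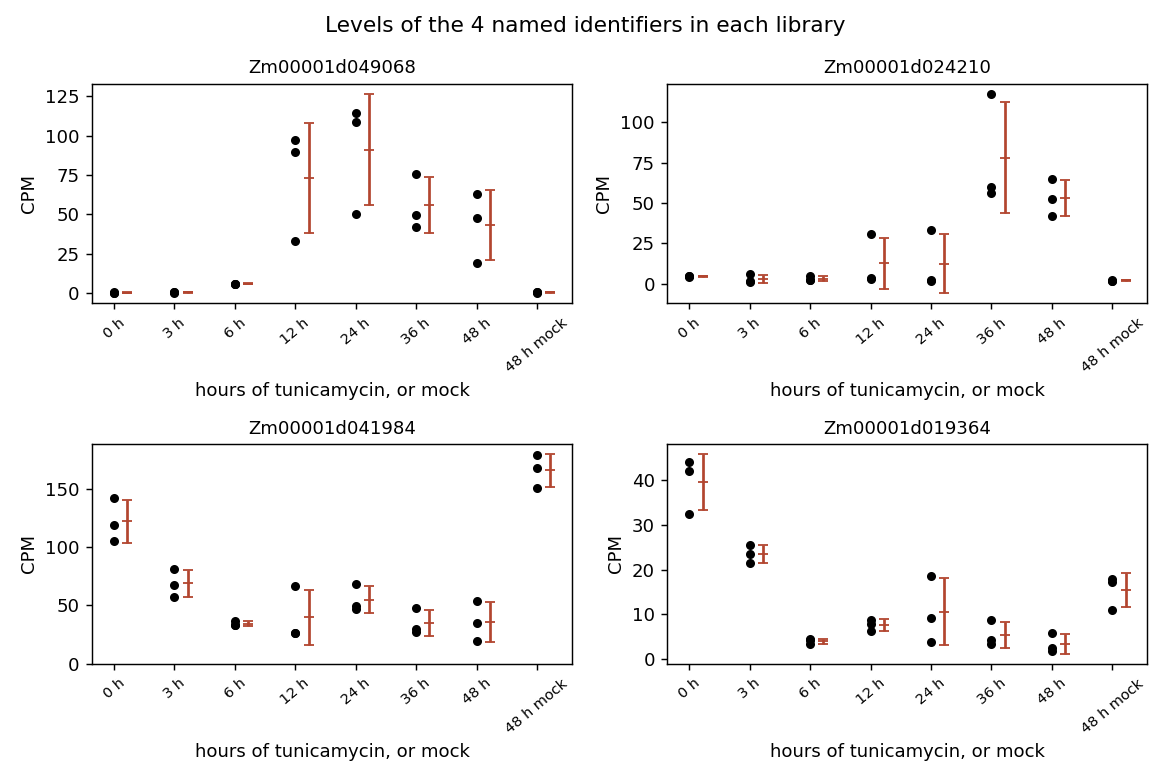
CPM of the 4 named identifiers (vertical) in each group (horizontal); black points are the 3 libraries and the red mark with bars is their mean ± SD. Zm00001d049068 goes from 0.286 CPM in the mock to 43.4 CPM at 48 h, and Zm00001d041984 from 165.6 to 36.0 CPM.

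The mock seedlings of 48 h were set against 0 h to see what changed without tunicamycin. There were 219 genes that rose and 271 that fell, with median log2 fold changes of 0.71 and -0.90. None of the 4 named identifiers passed the test here. Zm00001d019364 came closest, with 39.5 ± 6.25 CPM at 0 h and 15.3 ± 3.80 CPM in the mock (adjusted p = 0.0881, edgeR), and Zm00001d049068 stood at 0.236 and 0.286 CPM. With the library number as a block, 1412 genes were called, 682 higher and 730 lower. The count of 490 became 41, 23 or 1328 without library I, II or III of 0 h and 45, 135 or 23 without library I, II or III of the mock, and it was 1037 on lane 6, 29 on lane 7 and 18 with libraries I and II summed within each lane (8 higher and 10 lower). More genes were higher than lower without library III of 0 h (869 and 459).

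After 3 h of tunicamycin, 1966 genes rose and 1760 fell against 0 h. The median log2 fold change was 0.76 among the risen genes and -0.79 among the fallen genes. At least 4-fold changes were found for 176 risen and 71 fallen genes. The named identifiers did not pass the test at 3 h. Zm00001d041984 was at 68.6 ± 11.8 CPM against 121.8 ± 18.4 CPM at 0 h (adjusted p = 0.0944, edgeR), and Zm00001d049068 was at 0.436 CPM against 0.236 CPM. The total of 3726 became 1800 or 1675 without library I or II of 0 h and 2210, 2055 or 1986 without library I, II or III of 3 h. It was 5675 with only these groups in the model and 2364 with libraries I and II summed within each lane.

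At 6 h, 3342 genes rose and 3285 fell against 0 h. The fallen genes had the wider change, with a median log2 fold change of -0.89 against 0.71 for the risen genes, and 1369 fallen and 858 risen genes changed at least 2-fold. Zm00001d049068 rose to 5.73 ± 0.288 CPM (log2 fold change 4.54, SE 0.64, adjusted p = 0.000234, edgeR). Its 0 h libraries held 10, 2 and 3 reads, so the size of its changes against 0 h rests on a low reference. Zm00001d019364 fell by 3.32 on the log2 scale to 3.97 ± 0.560 CPM (SE 0.47, adjusted p = 0.000234, edgeR), and Zm00001d041984 fell to 34.3 ± 2.24 CPM (adjusted p = 0.00128, edgeR). Zm00001d024210 did not pass the test, at 3.10 ± 1.57 CPM against 4.66 ± 0.331 CPM. The total of 6627 became 3461 or 3280 without library I or II of 0 h and 3536 or 3563 without library I or II of 6 h.

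At 12 h, 217 genes rose and 88 fell against 0 h, with median log2 fold changes of 1.20 and -1.61. Zm00001d049068 rose to 73.3 ± 34.9 CPM (log2 fold change 8.22, SE 0.64, adjusted p = 3.21e-07, edgeR). Zm00001d041984 and Zm00001d019364 fell to 39.7 ± 23.5 and 7.65 ± 1.30 CPM (adjusted p = 0.0176 and 0.00781, edgeR). Zm00001d024210 averaged 12.6 ± 15.8 CPM, with 3.7, 3.1 and 30.8 CPM in libraries I, II and III, and did not pass the test (adjusted p = 0.487, edgeR). Library III of 12 h lay apart from libraries I and II, and the 217 risen and 88 fallen genes became 320 and 291 without it. Without library I or II of 12 h, 118 or 142 genes were called, of which 17 or 25 fell. The risen and fallen genes became 99 and 36, 94 and 29 or 699 and 178 without library I, II or III of 0 h and 505 and 356 with DESeq2, and the total of 305 became 136 with only these groups in the model.

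At 24 h, 2375 genes rose and 1941 fell against 0 h. The median log2 fold changes were 0.84 and -0.73. Zm00001d049068 stood at 91.1 ± 35.5 CPM, the highest mean of its 8 groups (log2 fold change 8.53, SE 0.65, adjusted p = 1.83e-07, edgeR). Zm00001d041984 fell to 54.9 ± 11.6 CPM (adjusted p = 0.0227, edgeR) and Zm00001d019364 to 10.6 ± 7.50 CPM (adjusted p = 0.00623, edgeR). Zm00001d024210 did not pass the test, at 12.4 ± 18.2 CPM (adjusted p = 0.273, edgeR). The lanes of this group disagreed, with a correlation of 0.215 for library I and 0.0108 for library III where other groups had 0.393 to 0.901. The count was 10422 on lane 6 and 1072 on lane 7, where the 24 h group held libraries I and III only. The total of 4316 became 747 with only these groups in the model, 1872 with libraries I and II summed within each lane, and 2382 or 2303 without library I or II of 0 h.

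At 36 h, 996 genes rose and 1066 fell against 0 h, with median log2 fold changes of 0.97 and -0.92. Zm00001d024210 rose to 77.9 ± 34.5 CPM, its highest mean, and passed the test against 0 h (log2 fold change 4.06, SE 0.96, adjusted p = 0.0154, edgeR). Zm00001d049068 was at 55.7 ± 17.7 CPM (adjusted p = 6.95e-07, edgeR). Zm00001d041984 and Zm00001d019364 fell to 34.7 ± 10.99 and 5.40 ± 2.90 CPM (adjusted p = 0.00409 and 0.00143, edgeR). The total of 2062 became 480, 499 or 3487 without library I, II or III of 0 h and 925, 1055 or 818 without library I, II or III of 36 h. It was 3505 with DESeq2, 3878 with the 24 h libraries out of the model and 3602 with the block. On lane 6 it was 1256, on lane 7 3143, and with libraries I and II summed within each lane 1103. The larger direction turned in 8 of 17 settings, as without library III of 0 h (2015 higher and 1472 lower).

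At 48 h, 2882 genes rose and 2824 fell against 0 h, where the comparison with the mock called 112 genes in all. The median log2 fold changes were 0.76 and -0.88. All 4 named identifiers passed the test: Zm00001d049068 and Zm00001d024210 rose by 7.46 and 3.51 on the log2 scale (adjusted p = 1.49e-06 and 0.0126, edgeR), and Zm00001d041984 and Zm00001d019364 fell by 1.76 and fell by 3.55 (adjusted p = 0.00204 and 0.000161, edgeR). They were chosen at 48 h against mock, which uses the same 48 h tunicamycin libraries, so these calls are not separate support. The total of 5706 became 2788 or 2619 without library I or II of 0 h and 3640 without library II of 48 h.

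**Figure D3:**
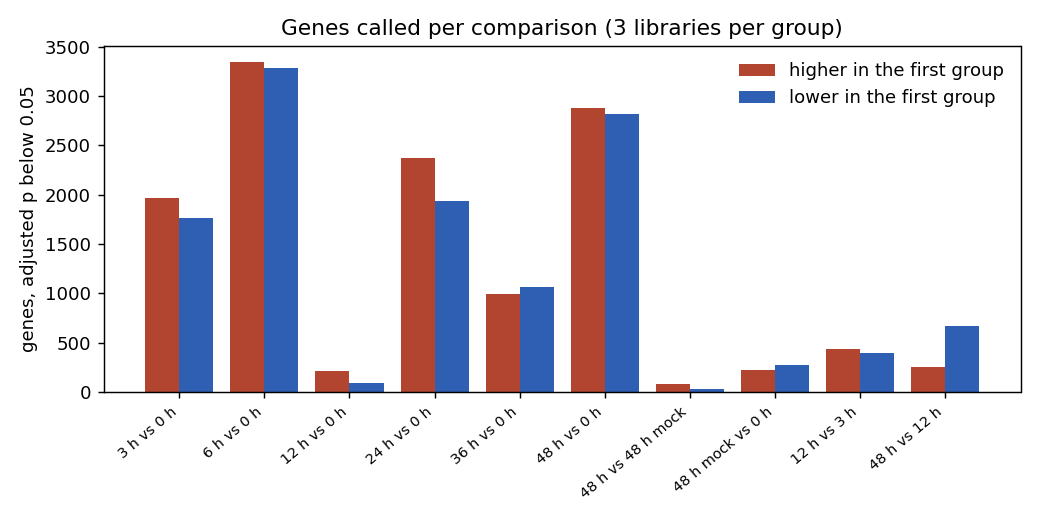
Number of genes called at an adjusted p below 0.05 (vertical) in each of the 10 comparisons (horizontal), with red bars for genes higher and blue bars for genes lower in the group named first. The bars run from 80 and 32 genes at 48 h against mock to 3342 and 3285 genes at 6 h against 0 h.

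Early and sustained treatment were compared directly at 12 h against 3 h. There were 437 genes higher and 398 lower at 12 h, with median log2 fold changes of 0.89 and -0.99. Zm00001d049068 was higher at 12 h by 7.36 on the log2 scale (SE 0.59, adjusted p = 8.75e-07, edgeR), and Zm00001d019364 was lower, with 7.65 ± 1.30 against 23.5 ± 1.98 CPM (adjusted p = 0.0456, edgeR). The 3 h libraries held 5, 8 and 18 reads of Zm00001d049068. The total of 835 became 447, 379 or 321 without library I, II or III of 3 h and 311 or 377 without library I or II of 12 h. It was 2165 on lane 6, 414 on lane 7, 354 with libraries I and II summed within each lane, and 1583 with DESeq2, and the block gave 600 lower genes.

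Late treatment was compared with its middle at 48 h against 12 h. There were 252 genes higher and 669 lower at 48 h, with median log2 fold changes of 0.74 and -1.003. None of the 4 named identifiers passed this test. Zm00001d049068 was at 43.4 ± 22.2 CPM at 48 h and 73.3 ± 34.9 CPM at 12 h (adjusted p = 0.28, edgeR), and Zm00001d024210 at 53.0 ± 11.3 and 12.6 ± 15.8 CPM (adjusted p = 0.165, edgeR). The total of 921 became 46, 47 or 3158 without library I, II or III of 12 h (1370 higher and 1788 lower without III) and 268, 85 or 241 without library I, II or III of 48 h. It was 31 with only these groups in the model, where 18 were higher and 13 lower and 23 were shared with the main fit, 148 with libraries I and II summed within each lane, 47 on lane 7 and 2082 with DESeq2.

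Early and late responses were set against each other in comparisons that share no library, 3 h against 0 h and 48 h against mock. Genes higher in both numbered 16, where independent lists would share 6.62 (one-sided Fisher's exact test, p = 0.000756, adjusted p = 0.00302 over 4 overlaps). Genes lower in both numbered 6, where 2.37 would be shared (exact p = 0.0281, adjusted p = 0.0562), which did not pass after adjustment. Opposite directions were found for 1 gene each way, against 2.65 and 5.93. The test takes genes as independent draws, so its p-value does not measure the spread between libraries. Both lists also come from the model with 1 shared estimate of the spread. Fold change followed recovered length in both comparisons (Spearman correlations across genes of 0.244 and 0.208). The overlap was not tested among genes of like length.

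The 80 genes that rose at 48 h against mock were then followed at the other times against 0 h, in libraries outside the groups compared to choose them. The shared estimate of the spread did use these libraries. All times have the same 0 h libraries as reference, so they are not separate support for each other. The median log2 fold change of the 80 genes was 0.22 at 3 h, 0.55 at 6 h, 1.40 at 12 h, 1.48 at 24 h and 1.48 at 36 h. Camera called the set higher at each of these times (adjusted p from 3.31e-80 at 12 h to 0.000116 at 3 h). With an estimated correlation the calls held at 12, 24 and 36 h (adjusted p = 0.00127, 0.00623 and 0.00403) and were lost at 3 and 6 h (adjusted p = 0.367 and 0.145). Single genes of the set that passed their own test numbered 16 at 3 h, 32 at 6 h, 56 at 12 h, 68 at 24 h and 73 at 36 h. Between 3 and 12 h the set rose by a median of 1.15 on the log2 scale in the direct comparison (adjusted p = 0.00623 with an estimated correlation). Its median level went from 19.6 CPM at 0 h to 25.5, 31.6, 60.5, 68.7, 56.0 and 53.1 CPM over the 6 treatment times.

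The 32 genes that fell at 48 h against mock had median log2 fold changes against 0 h of -0.52 at 3 h, -1.01 at 6 h, -0.78 at 12 h, -0.94 at 24 h and -1.18 at 36 h. Here too all times share the 0 h libraries. The set was called lower at every one of these times by camera, and with an estimated correlation at 6, 12, 24 and 36 h (adjusted p = 0.0353, 0.01, 0.0323 and 0.00832) but not at 3 h (adjusted p = 0.181). Without library III of 12 h in the model, those at 6 and 24 h were lost (adjusted p = 0.0581 and 0.0507 with an estimated correlation) with medians still at -1.01 and -0.94. Of its genes, 6 passed their own test in this direction at 3 h, 22 at 6 h, 8 at 12 h, 19 at 24 h and 24 at 36 h. Between 3 and 12 h its median moved by -0.38, a call that was lost with an estimated correlation (adjusted p = 0.196).

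The genes called at 3 h were followed against the 48 h mock, again in libraries outside the groups compared to choose them but within the shared estimate of the spread. All times have the same mock libraries as reference, so they are not separate support for each other. The 1966 genes that rose at 3 h had a median log2 difference from the mock of 0.24 at 6 h, -0.09 at 12 h, -0.01 at 24 h, -0.03 at 36 h and 0.15 at 48 h. The 1760 genes that fell had -0.24, 0.16, -0.04, 0.05 and -0.16. Both sets were called in their own direction at 6 h, also with an estimated correlation (adjusted p = 0.0323 and 0.0125). At 12 h both were called in the opposite direction and at 48 h in their own, and these calls were lost with an estimated correlation (adjusted p = 0.536 and 0.196 at 12 h, 0.139 and 0.103 at 48 h). At 24 and 36 h neither set was called. Set directly between 12 and 48 h, the genes that fell at 3 h moved by a median of -0.31 (adjusted p = 0.0323 with an estimated correlation) and those that rose by 0.26 (adjusted p = 0.115 with an estimated correlation). Library III stood apart from I and II both at 12 h (16.7 against -51.2 and -45.4 on the first component) and in the mock (53.1 against -20.8 and -21.7). Without library III of 12 h or of the mock, the risen set lost its call at 12 h (adjusted p = 0.112 and 0.115) and, with an estimated correlation, that at 6 h (adjusted p = 0.0507 and 0.064). The risen set's medians were then -0.10 and -0.04 at 12 h and 0.24 and 0.29 at 6 h. Without library III of the mock they were 0.04 at 24 h and 0.03 at 36 h, of the other sign than with it, and the fallen set had 0.03 at 36 h. From 12 to 48 h the fallen set moved by -0.29 without library III of 12 h, and the call was lost (adjusted p = 0.134 with an estimated correlation).

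**Figure D4:**
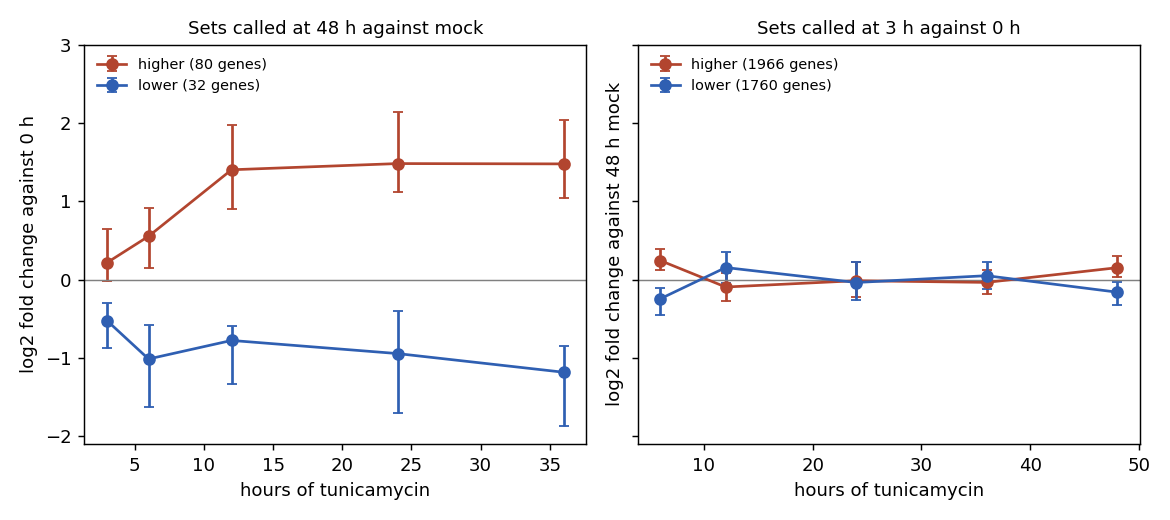
Median log2 fold change (vertical, bars from the lower to the upper quartile of genes) against hours of tunicamycin (horizontal); left, the 80 risen and 32 fallen genes of 48 h against mock, followed against 0 h, and right, the 1966 risen and 1760 fallen genes of 3 h against 0 h, followed against the 48 h mock. The risen set at left has its medians at 0.22, 0.55, 1.40, 1.48 and 1.48.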

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

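Levels under tunicamycin differed between treatment times for 2 of the 4 named identifiers, by a direct test of 12 h against 3 h. Neither time has its own mock, so elapsed time and tunicamycin are not separated here. Zm00001d049068 was higher at 12 h by 7.36 on the log2 scale (SE 0.59, adjusted p = 8.75e-07, edgeR), in all 3 libraries. Its 3 h libraries held 5, 8 and 18 reads, so the size of the change rests on a low reference. Zm00001d019364 differed by -1.62 (SE 0.44, adjusted p = 0.0456, edgeR), also in all 3 libraries. In the 48 h mock against 0 h it also stood lower, by -1.36, but did not pass the test (adjusted p = 0.0881, edgeR). Neither differed between 48 h and 12 h past the threshold (adjusted p = 0.28 and 0.131, edgeR).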

How the results depend on the processing

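The regrouping by lane, the model without 24 h, the set-by-time tests and their alternatives were chosen after the data had been seen, the rest before. Median-of-ratios scaling, no low-count filter (which removed 0 genes and so tests nothing) and a minimum of 5 CPM kept all 10 counts of called genes within 1.5 times, and median-of-ratios scaling kept at least 97.3% of the called genes in each comparison. The cause of the changes below was not tested. A library left out takes away reads and degrees of freedom, and a single lane holds fewer reads. Neither accounts for counts that rose with less data, as for mock against 0 h, to 1328 without library III of 0 h. With each library left out in turn, the counts ranged from 1675 to 3988 at 3 h, 3280 to 7233 at 6 h, 118 to 877 at 12 h, 2303 to 4576 at 24 h, 480 to 3487 at 36 h and 2619 to 6421 at 48 h against 0 h. They ranged from 37 to 192 for 48 h against mock, 23 to 1328 for mock against 0 h, 311 to 701 for 12 h against 3 h and 46 to 3158 for 48 h against 12 h. Leaving out library I or II of 0 h lowered every count against 0 h, and leaving out library III of 0 h raised each of them except that of 24 h (4066). Which direction held more of the called genes turned under at least 1 setting in 8 of the 10 comparisons, all but 12 h against 0 h and 48 h against mock. Where totals stayed within 1.5 times, 132 genes rose at 12 h on lane 6, 1555 at 24 h without library II of 24 h and 1874 at 48 h against 0 h without library III of 48 h, and 2797 fell at 3 h on lane 6 and 1791 at 48 h against 0 h on lane 7.

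With the replicate block, 537 genes were called at 12 h, 3602 at 36 h and 1412 in the mock against 0 h, and 2079 at 48 h against 12 h. It moved no other total by over 1.5 times, though the lower genes at 12 h against 3 h went from 398 to 600. At 48 h against mock it ended no call of a named identifier. No set call with the preset correlation ended, and the estimated correlation was not run with the block. Equal numbers did not pair the libraries at 3, 12, 24, 36 and 48 h against 0 h and at 48 h against 12 h, where the lowest correlations were 0.0752, 0.0833, 0.017, -0.022, 0.026 and 0.0907. Every library correlated best with its own number at 3 h against 0 h and at 48 h against 12 h, but not in the other 4. With only the groups compared in the model, counts were 5675 at 3 h, 136 at 12 h and 747 at 24 h against 0 h, and 31 at 48 h against 12 h. DESeq2 called 861 genes at 12 h, 3505 at 36 h and 1591 in the mock against 0 h, 263 at 48 h against mock, 1583 at 12 h against 3 h and 2082 at 48 h against 12 h.

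Lane 6 alone gave 10422 genes at 24 h, 1256 at 36 h and 1037 in the mock against 0 h, 2165 at 12 h against 3 h and 1786 at 48 h against 12 h. Lane 7 alone gave 2396 at 3 h, 1072 at 24 h, 3143 at 36 h and 29 in the mock against 0 h, 414 at 12 h against 3 h and 47 at 48 h against 12 h. On lane 7 the 24 h group held libraries I and III only. With libraries I and II summed within each lane, counts were 2364 at 3 h, 178 at 12 h, 1872 at 24 h, 1103 at 36 h, 3744 at 48 h and 18 in the mock against 0 h, 354 at 12 h against 3 h and 148 at 48 h against 12 h. Without the 24 h libraries in the model, counts were 527 at 12 h, 3878 at 36 h and 1472 in the mock against 0 h, 1354 at 12 h against 3 h and 1917 at 48 h against 12 h.

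Grouping by title, which adds lanes of different libraries together, gave 31 genes at 3 h, 3928 at 6 h, 4616 at 12 h, 9074 at 24 h, 8317 at 36 h, 28 at 48 h and 2038 in the mock against 0 h, and 1732 at 12 h against 3 h. At 48 h against mock it gave 0 genes with edgeR, with 3741 at an unadjusted p below 0.05, and DESeq2 was not run on it. Zm00001d024210 (-1.99) and Zm00001d019364 (0.33) then had the opposite sign, and all 4 named identifiers missed the threshold (adjusted p from 0.158 to 0.938, edgeR). If the titles are right, the values of the report do not belong to the times they name. Under the 10 settings other than title grouping and left-out libraries, the named identifiers kept their signs at 48 h against mock, the comparison in which they were rerun. The only call that ended there was that of Zm00001d019364 with only the groups compared in the model (adjusted p = 0.115, edgeR).

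Of 38 set-by-time tests, 30 passed with the preset correlation, 12 with an estimated one, 30 with median-of-ratios scaling, 30 with the block and 31 with the regrouping by lane, and 29, 31 and 32 without library III of 12 h, of the mock or of both. The overlap of risen genes, 16, was 15, 13 and 20 with median-of-ratios scaling, the 5 CPM minimum and the block, where 6.58, 6.39 and 10.95 were expected (one-sided Fisher's exact test, adjusted p = 0.00811, 0.0198 and 0.0224). That of fallen genes, 6, was 6, 7 and 6, where 2.67, 2.40 and 3.87 were expected (exact adjusted p = 0.094, 0.0198 and 0.373), so it passed with the 5 CPM minimum alone. These overlap tests take genes as independent draws. The tests of fixed gene lists and the fit with lane 7 of library II of 24 h were planned and not run, as the identifiers have no names and that lane was not analysed here. In the simulation of 48 h against mock, 10% of genes changed 1.5-fold were recovered at the depth, fitted spread and number of these libraries, and depth was not varied on its own. Its libraries were drawn independently, around the same mean per gene in every group apart from the changed genes. The real libraries I and II lay close to each other in most groups, so these rates do not show how the test behaves on such libraries.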

Other observations

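The tests of the lane as the repeat and of library III of 12 h were chosen only after the result was seen, as were the sets followed over time and the lists of neighbouring identifiers other than the genes that rose at 6 h. The 3342 genes that rose and the 3285 that fell at 6 h against 0 h were followed between other times, in libraries outside the groups compared to choose them. From 3 to 12 h the risen genes moved by a median of -0.22 on the log2 scale and the fallen genes by 0.33, that is, against their own direction. From 12 to 48 h they moved by 0.28 and -0.45, in their own direction again. Camera called all 4 changes, but with an estimated correlation only that of the fallen genes from 12 to 48 h held (adjusted p = 0.0164, against 0.116 and 0.0765 from 3 to 12 h and 0.0765 for the risen genes from 12 to 48 h). Without library III of the mock in the model, that of the fallen genes from 3 to 12 h passed too (adjusted p = 0.0437 with an estimated correlation). Against the mock the fallen genes had median log2 differences of -0.09 at 3 h, 0.22 at 12 h, 0.03 at 24 h, -0.03 at 36 h and -0.23 at 48 h. None of these passed with an estimated correlation (adjusted p from 0.0765 to 0.888). Without library III of the mock, which stands apart, they were -0.19 at 3 h, 0.13 at 12 h, -0.06 at 24 h, -0.13 at 36 h and -0.34 at 48 h, and that at 48 h passed (adjusted p = 0.019 with an estimated correlation, the others from 0.106 to 0.662). The risen genes then had 0.20, -0.03, 0.06, 0.10 and 0.26 at these times. None of those passed with an estimated correlation (camera adjusted p from 0.068 to 0.807). The 80 genes that rose late had a median of 1.40 at 12 h against 0 h.

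In 6 of the 7 groups with both lanes of libraries I and II, that is, without 24 h, these libraries on the same lane varied less between each other than either did between its own lanes. At 12 h the order held by little (0.1485 on lane 6 against 0.1487 for the lanes of library I), and at 48 h it did not hold. The common biological coefficient of variation had a median of 0.0759 for I and II on lane 6 and 0.0578 on lane 7, against 0.161 for the lanes of library I and 0.13 for those of library II. Unequal depth of the lanes as the cause is argued against by thinning every lane to 2020493 reads, after which the order held in 5 of 7 groups, no longer at 12 h. The lane, not the library number, may mark the repeat of one preparation, a hypothesis found and tested on the same lanes. The labels speak otherwise, since outside the mock both lanes of a library carry one name and one index. Yet the chi-square per degree of freedom between such lanes was 5.07 to 71.3, beyond what counting alone gives. It was 6.13 to 7.34 between lanes of the mock, where the indices differ, and 1.81 to 12.1 between libraries I and II on lane 6. Depth was not equalised for it. These values argue against lanes of one library that differ by counting alone. What else differs between them was not tested, so the question stays open. If the lane marks the repeat, the 3 libraries of a group are not the 3 separate samples that the tests assume. Libraries I and III on the same lane had medians of 0.248 on lane 6 and 0.231 on lane 7, and the lanes of library III 0.171. The fit with libraries I and II summed within each lane still counts their lanes as separate samples. Whether its counts are nearer was not tested.

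The lane 6 samples of 24 h stood apart from lane 7 of the same libraries, with correlations of 0.215 for library I and 0.0108 for library III, where the 21 other pairs had 0.393 to 0.901. Low depth of those lanes is argued against, since after thinning to one depth the higher of the 24 h correlations was 0.166 and the lowest of the others 0.3. After removal of a trend with the recovered length, the higher 24 h correlation was 0.286 and the lowest of the others 0.385. This argues against a change tied to that length as the whole cause. The recovered lengths reach 128400 bp and may include introns, so a change tied to transcript length was not tested. The difference between the lanes did follow length at 24 h (Spearman correlations across genes of -0.503 and -0.295, the others -0.115 to 0.588). A mislabelled lane and a real difference between preparations stay open, and neither was tested.

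Genes that rose at 48 h against mock had a median length of 3803 bp and those that fell 1744 bp (two-sided permutation p = 0.0008), with 3513 bp over all genes. A length bias of the libraries may account for it, since the Spearman correlation of fold change with length across all genes was 0.208 there and 0.213 in the mock against 0 h, with no tunicamycin. Genes are not independent replicates. The late sets kept their course when the median fold change of genes of like recovered length was taken off, with medians of 1.38 and -0.75 at 12 h. A biological preference for short genes was not tested.

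The low count at 12 h against 0 h was tested for one library of the group that differs from the other 2. Without library III of 12 h the count was 611 in place of 305, and without library I or II it was 118 or 142, as this explanation predicts. Libraries I and II lay close to each other in most groups. Without their own library III, counts against 0 h fell at 3 h (3726 to 1986) and 36 h (2062 to 818). They also fell at 48 h (5706 to 3896) and in the mock (490 to 23). They rose little at 6 h (6627 to 6700) and 24 h (4316 to 4576). In proportion, the rise at 12 h was the largest of these. Against the mock, leaving out library III of 48 h raised the count from 112 to 192. Library III of 0 h moved the count further, to 877 when left out, against 135 or 123 without library I or II of 0 h, so library III of 12 h is not the only one the count rests on, and why it is low stays open.

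Genes with consecutive identifiers were tested for rising together at 6 h. Both were called higher in 264 of 12806 pairs, where permutation within expression deciles gave a mean of 258 and a 95th percentile of 283 (one-sided permutation p = 0.348), so neighbours did not rise together beyond chance in the list chosen for the test. Over all 20 lists of risen or fallen genes, 13 had an excess (1000 permutations per list, adjusted p from 0.00285, the smallest they gave, to 0.0446), but 9 of the 13 come from comparisons that share the 0 h libraries, and 3 rest on 1, 2 or 3 pairs (fallen and risen genes at 48 h against mock, fallen genes at 12 h). Of these, 10 stayed in excess among pairs that correlated at 0.9 or less. That cut kept 12749 of the 12806 pairs, so it could hardly change the counts. It cannot tell whether reads shared between consecutive identifiers are the cause.

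Each comparison was refitted on its 6 libraries under the 10 splits into 3 and 3, and in each comparison 1 split, the real one, gave as many genes. With 10 splits the share cannot fall below 0.1, which is too few for a share under 0.05. Every other split mixes both groups on each side, so a difference between the groups enters its spread and lowers its count. The other counts therefore do not show how many genes chance alone would call. Real count and highest other count were 5675 and 0 at 3 h, 6890 and 0 at 6 h, 136 and 5 at 12 h, 747 and 0 at 24 h, 2825 and 2 at 36 h, 5701 and 0 at 48 h and 364 and 0 in the mock, against 0 h. They were 93 and 0 for 48 h against mock, 793 and 0 for 12 h against 3 h and 31 and 0 for 48 h against 12 h.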
